A study of Mus musculus with 24 samples.

How the data were processed

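RNA from 24 tumours was sequenced, 6 in each of 4 treatment groups, and each tumour gave 1 library. Per the labels' protocols, RNA was purified on RNeasy columns, its integrity was read on a TapeStation, and the libraries were made by Novogene. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, FastQC 0.11.8, MultiQC 1.11, HISAT2 2.2.1 and StringTie 2.2.1, and the genome build was GRCm39. Their order, the program that counted reads per gene, the gene annotation and the strand setting are not given in the sources used here.

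The deposited count table gives whole-number counts for 55414 Ensembl genes with 1 column per tumour, not normalized, and every comparison was made from these counts. The deposited FPKM table and the deposited TPM table, as used here, cover 27854 genes of low expression, which took 0.0819 to 0.184% of each library's counts and reached a mean of at most 4.29 FPKM. The authors computed those FPKM and TPM values; 780 of their genes were among the genes tested, and they entered no comparison. Every column matched 1 sample by its title.

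Library totals ran from 19106205 to 34282319 counts, so a gene at 1 CPM (counts scaled to the library total) rested on 19.1 to 34.3 counts. Replicates of a group differed by far more than counting error (given below), and the p-values measure the spread between tumours. Gene symbols were matched by Ensembl ID to the GENCODE M21 annotation, an older build than that of the counts, which was used for names, sequence composition and transcript length, and for no coordinates. Of all genes, 52081 had a symbol, and of the genes tested, 15980; genes with no symbol took 0.26 to 0.55% of counts. Members of families with near-identical copies may share or split reads, so single values are uncertain for the H2, Gbp, Tgtp, Ifit, Klra, Ighv, Trbc and Hba genes, and without a stated strand setting a gene cannot be told from an overlapping antisense gene.

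Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr by group and a robust quasi-likelihood F test over all 24 libraries, with group as the only term and 20 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method across the 16029 genes tested, and a gene was called at an adjusted p under 0.05. Values are given as CPM, mean ± SD, and as log2 fold change ± SE, the SE being the fold change divided by the square root of its F statistic. Each treated group was compared with IgG2a, BRQ+PD-1 was compared with PD-1 and with BRQ+IgG2a, and an interaction contrast tested whether the brequinar effect differed with anti-PD-1.

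For gene groups, 37 lists of pathway genes and cell type markers (761 genes, 704 of them measured) were fixed before the data were examined, together with the comparisons, the tests, the processing alternatives and the rule for naming genes. Each list was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, with adjustment over the lists. The same lists were tested with a correlation estimated from the data, with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, and with an exact two-sided permutation test of the mean log2 CPM of a list per tumour over the 924 assignments of 12 tumours to 2 groups. That mean is called the list score. Members called were counted over all genes tested and also adjusted over the list alone.

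The named genes were the 5 called genes with the largest change each way in the comparisons with IgG2a and the 3 largest in the others, at a mean of at least 1 CPM and leaving out predicted genes; Dhodh, Cad, Umps, Chka, Pcyt1a, Ptgs2, Pdcd1, Cd274, Cd8a, H2-K1 and H2-Ab1 in every comparison; and up to 4 called members of each list by adjusted p, or the 2 most abundant members of a called list without a called member. The text takes about 30 of these for each comparison. Of these, 1 gene that the rule names is not reported here.

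The test was checked on counts simulated from the mean, library size and dispersion of each of 16029 genes, with known changes set in the BRQ+IgG2a libraries. For BRQ+IgG2a against IgG2a it recovered 32.9% of 70 genes changed 1.5-fold, 70.0% of 70 changed 2-fold and 88.3% of 60 changed 4-fold, and a further 30 genes of 1 simulated list were raised 1.5-fold. Of the 142 calls over all these genes and the unchanged ones, 6 were false. The genes were drawn independently in 1 run, with no tumours set apart by muscle, so this share need not hold for the real libraries. Among replicates of a group, the 60 pairs of libraries differed by 9.4 to 191 times the sampling noise, so none was taken as a copy of another.

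The alternatives were relative log expression factors, no expression filter, DESeq2 1.42.0, limma voom with sample quality weights, a replicate number block, a fit without robust dispersion, a fit of the 2 groups compared alone, and leaving out each library in turn. Chosen after seeing the data were leaving out the 4 libraries rich in muscle transcripts, leaving out the 2 libraries of lowest TMM factor, the muscle score as a covariate, the permutation test of list scores, and contrasts of each treatment averaged over the other. Labels of the libraries were also reassigned in 100 ways for each comparison, the real one included.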

Results

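Gene expression was profiled in 24 D4M tumours grown in C57BL/6 wild-type mice, D4M being a mouse melanoma line. The 4 groups held 6 tumours each, from mice given an IgG2a control antibody (IgG2a), an antibody against the T cell checkpoint receptor PD-1 (PD-1), brequinar with the control antibody (BRQ+IgG2a), or brequinar with anti-PD-1 (BRQ+PD-1). Brequinar (BRQ) inhibits dihydroorotate dehydrogenase, the mitochondrial enzyme of de novo pyrimidine synthesis encoded by Dhodh, and the design text gives the aim as the effect of the pair of treatments on the tumour environment. Library totals averaged 27.5 ± 2.51 M counts in IgG2a (mean ± SD, n = 6), 25.9 ± 4.89 M in PD-1, 24.1 ± 2.5 M in BRQ+IgG2a and 24.9 ± 3.5 M in BRQ+PD-1. Mitochondrial transcripts took 1.112 to 2.125% of counts. Of 55414 genes, 16029 passed the expression filter and were tested.

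Skeletal muscle transcripts set 4 of the 24 tumours apart: replicates 2 and 3 of IgG2a, replicate 6 of PD-1 and replicate 4 of BRQ+IgG2a. Acta1, the actin of skeletal muscle, reached 4070 to 14990 CPM in these libraries and at most 425 CPM in the other 20. The first principal component, with 42.4% of the variance, separated the same 4 libraries. The mean log2 CPM of the 17 measured muscle genes was 4.16 ± 4.71 in IgG2a, 2.46 ± 3.8 in PD-1, 2.48 ± 4.33 in BRQ+IgG2a and 0.87 ± 2.66 in BRQ+PD-1, which held none of the 4. These tumours are spread unevenly over the groups, although the exact permutation test of the score called no difference between groups. Counts of called genes that change without these libraries are given with each pairwise comparison and the interaction.

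**Figure D1:**
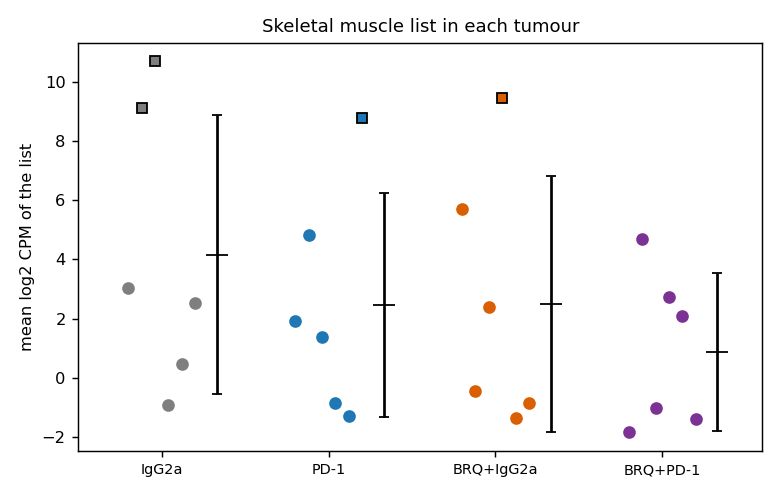
Mean log2 CPM of the skeletal muscle list in each tumour, by group, with the group mean ± SD at the side of the points. The 4 tumours rich in muscle transcripts, drawn as squares, stand apart from the other 20, and none of them is in BRQ+PD-1.

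The comparison of BRQ+IgG2a with IgG2a asks what brequinar changed without checkpoint blockade. Genes of T cells, of cytotoxic lymphocytes and of the interferon response were higher in the BRQ+IgG2a tumours. Cd4, the coreceptor of helper T cells, stood at 11.9 ± 3.48 CPM against 2.86 ± 1.08 in IgG2a (mean ± SD, n = 6 each), a log2 fold change of 2.05 ± 0.29 (SE). Cd8a, the coreceptor of cytotoxic T cells, stood at 19.1 ± 11.8 against 4.20 ± 3.23 CPM (2.18 ± 0.50), and Prf1, which encodes the pore-forming protein perforin, at 15.7 ± 9.52 against 2.82 ± 1.72 CPM (2.48 ± 0.37). Pdcd1, which encodes PD-1 itself, rose by 2.21 ± 0.43 and Cd274, which encodes its ligand PD-L1, by 1.45 ± 0.27. All of these were above the IgG2a mean in 6 of 6 BRQ+IgG2a tumours, with edgeR adjusted p from 0.000398 (Cd4) to 0.0147 (Cd8a).

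In the same comparison, 475 genes rose and 79 fell among 16029. Scara5 (ENSMUSG00000022032), a scavenger receptor that takes up ferritin, went from 3.73 ± 3.17 to 55.5 ± 23.7 CPM, a log2 fold change of 3.89 ± 0.53 with adjusted p 0.000414. H2-M2 (ENSMUSG00000016283), a nonclassical MHC class I gene, rose by 4.01 ± 0.84, from 0.477 ± 0.321 to 7.86 ± 8.75 CPM, and Klri2, a lectin-like receptor of natural killer cells, by 2.59 ± 0.44. Klra17, of the Ly49 receptor family, and Tox, a transcription factor of exhausted T cells, rose by 3.03 ± 0.75 and 2.90 ± 0.69. Large falls were Fcna, the lectin ficolin A, at -2.44 ± 0.54, Adm2, an adrenomedullin-type peptide, at -1.99 ± 0.49, Npl, a sialic acid lyase, at -1.92 ± 0.36, the serine protease gene Prss22 at -1.78 ± 0.50 and the small GTPase gene Rab15 at -1.73 ± 0.38. Scara5, H2-M2, Klri2, Fcna, Npl and Rab15 stayed called in all 12 fits that left out 1 library. Tox was called in 10 of these fits (adjusted p 0.0602 without BRQ+IgG2a replicate 6), Adm2 in 9 (0.0881 without IgG2a replicate 4), Klra17 in 6 (0.0765 without BRQ+IgG2a replicate 3) and Prss22 in 3 (0.131 without BRQ+IgG2a replicate 6). Among the called genes described here for this comparison, Tox, H2-Ab1, Ccr8, Fcgr4, Adgre1, Xcr1, Cxcl16, Samhd1, Lpcat2 and Lpin3 went the stated way in 5 of 6 tumours and the others in 6 of 6. The count of 554 genes became 309 without IgG2a replicate 5, 308 without IgG2a replicate 6, 363 without BRQ+IgG2a replicate 1, 258 without BRQ+IgG2a replicate 6 and 1179 without BRQ+IgG2a replicate 5, where 813 rose and 366 fell, so the number of falls depends on that tumour. Without the 4 muscle-rich libraries it was 657, with 443 of the 554 among them.

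Lymphocyte lists were higher in BRQ+IgG2a. The T cell, checkpoint and regulatory T cell scores were above the IgG2a mean in 6 of 6 tumours, and the cytotoxic score in 5 of 6. Of the 20 T cell genes measured, 13 rose and 0 fell (19 rose when adjusted over the list alone), among them the costimulatory receptor gene Icos (2.12 ± 0.46). Of 21 genes of cytotoxic lymphocytes, 13 rose (19 adjusted over the list alone), and of 16 checkpoint and exhaustion genes 8 rose (9 adjusted over the list alone), including Havcr2, which encodes TIM-3 (0.96 ± 0.20). Regulatory T cell genes numbered 4 of 11 among the rises (7 rose and 1 fell when adjusted over the list alone), with Il2rb, an interleukin-2 receptor chain, at 1.94 ± 0.42 and the chemokine receptor gene Ccr8 at 2.37 ± 0.62. Median log2 fold changes were 1.67 for T cells, 1.75 for cytotoxic lymphocytes, 0.77 for checkpoint genes and 0.88 for regulatory T cells. Each of these 4 lists was called by camera at the preset correlation and lost the call with an estimated correlation, at adjusted p = 0.0929, 0.0997, 0.0705 and 0.197. The muscle list went the other way, with a median of -1.68 and no member called. Without the 4 muscle-rich libraries, 17 T cell and 16 cytotoxic genes rose.

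Antigen presentation and interferon genes made up the other large group in BRQ+IgG2a. Of 30 genes of the interferon gamma response, 19 rose (29 adjusted over the list alone), such as the guanylate-binding GTPases Gbp9 (1.30 ± 0.19) and Gbp6 (1.89 ± 0.31). Of 30 genes of the type I interferon response, 21 rose (29 adjusted over the list alone), among them the ADP-ribosyltransferase gene Parp14 (0.98 ± 0.15) and Stat2, a subunit of the interferon transcription factor (0.97 ± 0.17). MHC class I presentation had 12 of 22 genes higher (19 adjusted over the list alone), with H2-K1, a classical heavy chain, at 2071 ± 415 against 1232 ± 362 CPM (0.75 ± 0.17) and its transactivator Nlrc5 at 0.88 ± 0.15. MHC class II presentation had 8 of 12 higher (10 adjusted over the list alone), with H2-Ab1 at 2.01 ± 0.46 and Cd74, the invariant chain, at 2.15 ± 0.41. The MHC class II score was above the IgG2a mean in 5 of 6 tumours. Its lowest value in BRQ+IgG2a, 4.589, was under the lowest in IgG2a, 4.691. No measured member of these 4 lists fell. Their medians were 1.43, 0.996, 0.72 and 1.39, and with an estimated correlation their adjusted p were 0.0705, 0.0705, 0.0705 and 0.181. The counts without the muscle-rich libraries were 25, 25, 16 and 8.

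**Figure D2:**
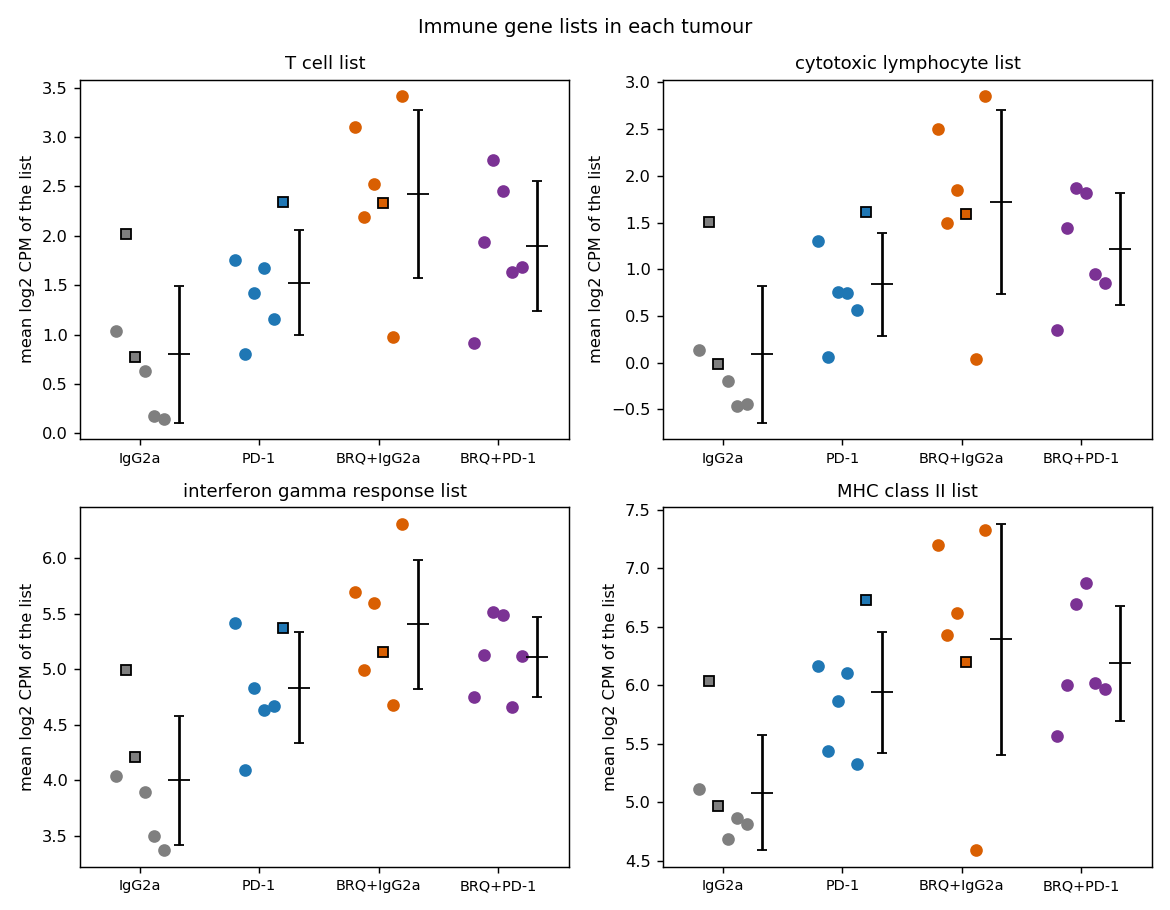
Mean log2 CPM per tumour of the immune lists, by group, with the group mean ± SD at the side of the points and squares for the tumours rich in muscle transcripts. The T cell list averaged 0.80 in IgG2a, 1.52 in PD-1, 2.42 in BRQ+IgG2a and 1.90 in BRQ+PD-1.

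Myeloid markers split in BRQ+IgG2a. Of 23 macrophage genes 3 rose (4 rose and 1 fell when adjusted over the list alone): the costimulatory ligand gene Cd86 (0.78 ± 0.14), the Fc receptor gene Fcgr4 (1.79 ± 0.40) and Adgre1, which encodes F4/80 (0.71 ± 0.19). Of 14 dendritic cell genes 4 rose (8 adjusted over the list alone), including Itgax, which encodes CD11c (1.31 ± 0.27), and Xcr1, a chemokine receptor of cross-presenting dendritic cells (1.5 ± 0.41). The dendritic cell list was called, with adjusted p = 0.237 at an estimated correlation, and the macrophage list was not. Of 17 neutrophil genes Csf3r alone rose (1.02 ± 0.24), and of 27 cytokine and chemokine genes Cxcl16 (0.77 ± 0.17) and Ccl3 (1.46 ± 0.33; 3 adjusted over the list alone). No B and plasma cell gene of 11 was called, although the list was, at a median of 0.49 (adjusted p = 0.814 with an estimated correlation); Ighm, the IgM heavy chain, had a log2 fold change of 1.65 ± 0.68 (adjusted p 0.243).

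The enzymes of the pathway that brequinar blocks did not pass the test in BRQ+IgG2a against IgG2a. Dhodh (ENSMUSG00000031730) stood at 12.5 ± 1.19 CPM against 13.8 ± 1.88, a log2 fold change of -0.14 ± 0.11 (adjusted p 0.638). Cad and Umps, the other genes of de novo UMP synthesis, had -0.06 ± 0.11 and -0.07 ± 0.12, and none of the 9 genes of their list was called. Of the CDP-choline pathway, Chka, choline kinase alpha, had -0.08 ± 0.12 and Pcyt1a, the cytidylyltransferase that makes CDP-choline, 0.15 ± 0.12. Of the 27 genes of phospholipid synthesis, Lpcat2, an acyltransferase of myeloid cells, rose by 0.80 ± 0.17 and Lpin3, a phosphatidate phosphatase, had -0.79 ± 0.22 and fell. Ptgs2, the inducible cyclooxygenase gene, had -0.30 ± 0.85, and of the 19 prostaglandin and leukotriene genes the receptor gene Ptger4 rose (0.72 ± 0.17; 2 rose adjusted over the list alone). Samhd1, a dNTP hydrolase, was the 1 called of 21 salvage genes (0.84 ± 0.22). Stress and growth lists were lower with few genes called: Nop56, a nucleolar protein gene, among 30 ribosome biogenesis genes (-0.33 ± 0.08; 3 adjusted over the list alone), Chac1, a glutathione-degrading enzyme, among 26 integrated stress response genes (-1.37 ± 0.37) and Sesn2, a stress-induced sestrin, among 26 p53 targets (-0.66 ± 0.17). These 3 lists were called, with adjusted p = 0.386, 0.501 and 0.290 at an estimated correlation. Nuclear oxidative phosphorylation genes were called as a list at a median of -0.14 with no member called (adjusted p = 0.825 with an estimated correlation), and the list changed direction without the muscle-rich libraries (adjusted p 0.953). No member was called of the endothelial, fibroblast, melanocytic, neural crest, keratinocyte, mast cell, adipocyte, erythroid, S phase, mitosis, mitochondrially encoded oxidative phosphorylation, ferroptosis, cholesterol, fatty acid or hypoxia lists (1 keratinocyte gene was lower when adjusted over the list alone).

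The comparison of PD-1 with IgG2a asks what the antibody changed alone. It called 3 genes, all higher and all in 6 of 6 PD-1 tumours above the IgG2a mean. Tlr12 (ENSMUSG00000062545), a Toll-like receptor of profilin, went from 5.30 ± 1.79 to 17.8 ± 5.29 CPM (mean ± SD, n = 6 each), a log2 fold change of 1.75 ± 0.30. Cd300a, an inhibitory receptor of myeloid cells, went from 7.15 ± 0.939 to 14.0 ± 2.38 CPM (0.97 ± 0.17), and Runx3, a transcription factor of CD8 T cells, from 17.6 ± 1.39 to 26.9 ± 2.42 CPM (0.62 ± 0.11). Their edgeR adjusted p was 0.0402 each. Without PD-1 replicate 2 Cd300a and Runx3 remained called, and without any other single library of the 2 groups no gene was called. Without the 4 muscle-rich libraries 2 genes were called, 1 higher and 1 lower, and none of these 3. Pdcd1 (1.21 ± 0.42, adjusted p 0.514), Cd8a (0.91 ± 0.48, 0.782), Cd274 (0.78 ± 0.27, 0.514), H2-Ab1 (1.21 ± 0.45, 0.560) and H2-K1 (0.30 ± 0.17, 0.798) had positive fold changes that did not pass. Dhodh (-0.09 ± 0.11), Cad (0.11 ± 0.11), Umps (0.05 ± 0.12), Chka (0.19 ± 0.12), Pcyt1a (-0.04 ± 0.12) and Ptgs2 (0.21 ± 0.84) did not pass either.

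Among the lists in PD-1, the interferon gamma response had 0 of 30 genes called across all genes and 15 higher when adjusted over the list alone, with a median log2 fold change of 0.74 and the GTPase gene Gbp2 at 0.98 ± 0.28 (adjusted p 0.392). MHC class II presentation had 6 of 12 higher adjusted over the list alone (median 0.86), and T cells 1 of 20 (0.60). B and plasma cells had 5 of 11 higher adjusted over the list alone (0.98), but the list was above the IgG2a mean in 4 of 6 tumours and highest in the muscle-rich PD-1 replicate 6 (mean log2 CPM 3.65, next tumour 0.686). Without the muscle-rich libraries its median was 0.39, with no member called across all genes. The cytotoxic, MHC class I and type I interferon lists had medians of 0.76, 0.31 and 0.38 and no member called either way. These zeros are by edgeR, with 1036 genes of the 16029 at an unadjusted p under 0.05; DESeq2 called 35 genes in all and limma voom 6. Camera at the preset correlation called 20 lists, 15 higher and 5 lower, and 0 with an estimated correlation, where the interferon gamma list had adjusted p = 0.390. The muscle list was among the lower ones at a median of -2.43 (adjusted p = 0.721 with an estimated correlation).

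The comparison of BRQ+PD-1 with IgG2a gives the change under both treatments. Scara5 rose by 3.20 ± 0.52, to 34.4 ± 19 CPM, and H2-M2 by 4.36 ± 0.85, to 10.02 ± 9.17 CPM (mean ± SD, n = 6 each). Scml4 (ENSMUSG00000044770), a Polycomb-type gene, rose by 3.10 ± 0.41 from 2.12 ± 1.02 to 18.2 ± 7.35 CPM. Ighv1-82, an antibody variable segment, and Apol7c, an apolipoprotein L gene, rose by 3.73 ± 0.999 and 2.91 ± 0.79, but were called in only 5 and 4 of 12 fits without 1 library (adjusted p 0.149 and 0.0994 without BRQ+PD-1 replicate 3). Moxd1, a monooxygenase gene, had -3.45 ± 0.83 and fell in 6 of 6 tumours, with adjusted p 0.0233 (0.057 without IgG2a replicate 1, and called in 10 of 12 fits without 1 library). The other large falls moved with muscle content: Klf15 (-5.57 ± 1.55), the metallothionein gene Mt3 (-4.38 ± 1.24), Stac3, a protein of muscle excitation-contraction coupling (-3.47 ± 0.98), and the glutathione transferase gene Gstp2 (-3.17 ± 0.85). Without the 4 muscle-rich libraries, Mt3 had -1.67, Stac3 -0.60 and Gstp2 -0.73, at adjusted p 0.484, 0.369 and 0.247; Klf15 then fell under the expression filter. The muscle list itself had a median of -5.99, with 0 of 17 genes called and 15 lower when adjusted over the list alone (adjusted p = 0.580 with an estimated correlation).

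Immune genes were also higher in BRQ+PD-1 than in IgG2a. The IgG2a tumours are the same as in BRQ+IgG2a against IgG2a, so this is no separate replication. The interferon gamma list had 14 of 30 genes higher (21 adjusted over the list alone; median 1.03), led by Gbp2 (1.53 ± 0.29) and Gbp9 (1.02 ± 0.19). MHC class II presentation had 6 of 12 higher (8 adjusted over the list alone), with Cd74 at 1.84 ± 0.40 and H2-Ab1 at 1.68 ± 0.45, and MHC class I 6 of 22 (15), with Nlrc5 at 0.76 ± 0.15. T cells had 3 of 20 higher (11 adjusted over the list alone), with Cd4 at 8.03 ± 3.63 against 2.86 ± 1.08 CPM (1.49 ± 0.28); cytotoxic lymphocytes 3 of 21 (10), with Prf1 at 1.78 ± 0.36; checkpoint genes 4 of 16 (8), with Pdcd1 at 1.71 ± 0.42; and the type I interferon response 3 of 30 (7). Cd274 rose by 1.41 ± 0.27 and Itgax, of the dendritic cell list (3 of 14 higher, 5 adjusted over the list alone), by 1.59 ± 0.27. Cd8a (1.58 ± 0.49) and H2-K1 (0.54 ± 0.17) missed the threshold at adjusted p 0.0675 each, and passed it without the muscle-rich libraries, at 0.0333 and 0.0122. In that fit 8 T cell, 9 cytotoxic, 18 interferon gamma and 11 MHC class I genes rose. The fit also left out IgG2a replicate 2, the highest IgG2a tumour for cytotoxic genes (mean log2 CPM 1.5, next tumour 0.133). Its removal lowers the control level of these genes, so the gain cannot be credited to muscle. Camera called 18 lists, 11 higher and 7 lower; with an estimated correlation none was called, and adjusted p was 0.358 for the interferon gamma and 0.412 for the T cell list.

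Genes of ribosome biogenesis were lower in BRQ+PD-1 than in IgG2a. Of 30, 11 fell (21 adjusted over the list alone; median -0.32), among them Nop56 (-0.45 ± 0.08), Polr1b, an RNA polymerase I subunit (-0.43 ± 0.09), Nop2, an rRNA methyltransferase (-0.48 ± 0.11), and Rrp9 (-0.51 ± 0.12). The list had adjusted p = 0.237 with an estimated correlation, and 5 of its genes fell without the muscle-rich libraries, at a median of -0.30. Serine and one-carbon enzymes of the integrated stress response list, Psph (-0.65 ± 0.18) and Shmt2 (-0.54 ± 0.15), fell with Chac1 (-1.30 ± 0.37), the 3 called of 26 (4 adjusted over the list alone). Of the p53 targets Sesn2 (-0.66 ± 0.17) and the exonuclease gene Aen (-0.43 ± 0.12) fell, 2 of 26 (6 adjusted over the list alone, and 1 higher). Slc29a2, a nucleoside transporter, fell by 0.65 ± 0.17. Nuclear oxidative phosphorylation genes had 0 of 30 called and 14 lower when adjusted over the list alone. Single genes of other lists were the cytokine gene Il1b (1.1 ± 0.31) and the chemokine gene Ccl12 (-0.75 ± 0.21), smooth muscle actin Acta2 (-1.28 ± 0.36), alpha globin Hba-a2 (-2.13 ± 0.58), Lpcat2 (0.65 ± 0.17) and Ptger4 (0.67 ± 0.17). The called genes described here for this comparison went the stated way in 6 of 6 tumours. Dhodh (-0.14 ± 0.11), Cad (-0.14 ± 0.11), Umps (-0.14 ± 0.12), Chka (-0.17 ± 0.12), Pcyt1a (0.33 ± 0.12) and Ptgs2 (0.40 ± 0.85) did not pass. In all 398 genes rose and 229 fell by edgeR, and the 627 became 260 without IgG2a replicate 1, 256 without IgG2a replicate 3, and 393, 355 and 263 without BRQ+PD-1 replicates 1, 2 and 3. It was 404 without the muscle-rich libraries, 330 higher and 74 lower. Without IgG2a replicate 1, IgG2a replicate 3 or BRQ+PD-1 replicate 3, the falls numbered 63, 63 and 66. The number of falls thus depends on the muscle-rich libraries and on single other libraries.

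**Figure D3:**
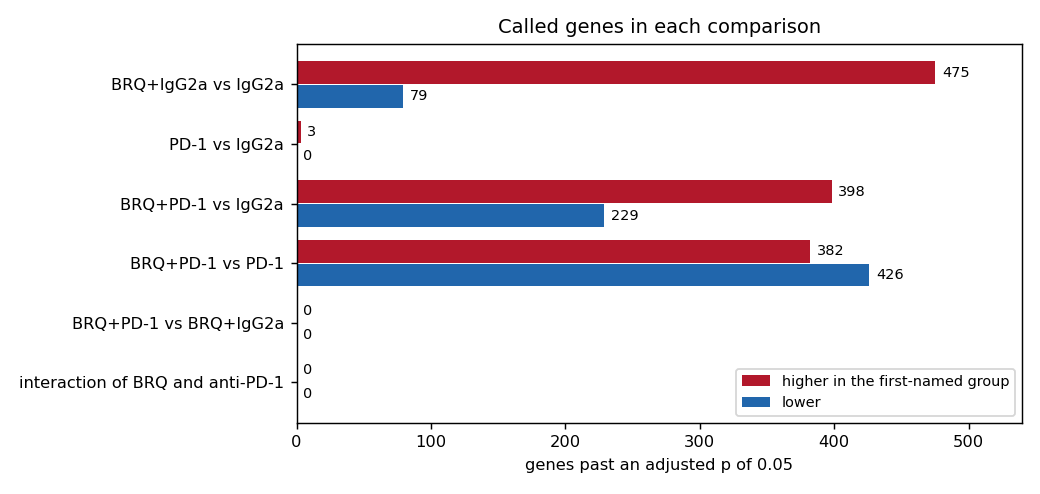
Number of genes called higher and lower in each comparison at an adjusted p under 0.05 (edgeR, 6 tumours per group). BRQ+IgG2a against IgG2a called 475 higher and 79 lower, and BRQ+PD-1 against BRQ+IgG2a called 0.

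The comparison of BRQ+PD-1 with PD-1 asks what brequinar added to the antibody. Ribosome biogenesis genes were lower together in the BRQ+PD-1 tumours: 17 of 30 fell and 0 rose (26 fell when adjusted over the list alone), with a median log2 fold change of -0.39. Nop2 went from 79.2 ± 16.5 to 46.8 ± 3.72 CPM (mean ± SD, n = 6 each), a log2 fold change of -0.76 ± 0.11 with edgeR adjusted p 0.000828, Nop56 from 105 ± 11.9 to 74.1 ± 6.67 CPM (-0.50 ± 0.08), and the box C/D snoRNP gene Nop58 and Rrs1 by -0.50 ± 0.10 and -0.55 ± 0.11. The mean log2 CPM of the list was 5.79 ± 0.0474 against 6.17 ± 0.138, lower in 6 of 6 tumours, with an exact permutation p of 0.00216 (adjusted 0.0400). With an estimated correlation the list had adjusted p = 0.0968, and without the muscle-rich libraries 10 of its genes fell, at a median of -0.35. The muscle list was lower too, at a median of -3.58 with no member called.

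Other stress genes fell in BRQ+PD-1 against PD-1. Of 26 p53 targets 6 fell (11 fell and 1 rose when adjusted over the list alone), among them Sesn2 (-0.94 ± 0.17), Aen (-0.54 ± 0.12), the ribosomal protein paralog gene Rps27l (-0.43 ± 0.12) and the RNA-binding protein gene Zmat3 (-0.48 ± 0.14). The exact permutation test of this list gave p 0.00216 (adjusted 0.0400), and the estimated correlation adjusted p = 0.109. Of 26 integrated stress response genes 5 fell (13 adjusted over the list alone), including the mitochondrial one-carbon enzymes Shmt2 (-0.67 ± 0.15) and Mthfd2 (-0.83 ± 0.22), Chac1 (-1.48 ± 0.37) and Ddit4, an inhibitor of mTORC1 (-0.67 ± 0.17). That list had adjusted p = 0.573 with an estimated correlation. Slc29a2 (-0.76 ± 0.17) and Dut, the dUTPase gene (-0.49 ± 0.14), fell among 21 salvage genes (2 rose and 3 fell when adjusted over the list alone), and the replication helicase gene Mcm2 (-0.57 ± 0.16) among 30 S phase genes. Without the muscle-rich libraries 4 p53 targets and 3 stress response genes fell.

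Mast cell proteases were higher in BRQ+PD-1 than in PD-1. Tpsb2 went from 11.0 ± 6.77 to 34.3 ± 20 CPM (1.64 ± 0.44) and Tpsab1 from 1.03 ± 0.457 to 3.67 ± 2.04 CPM (1.83 ± 0.49), the 2 called of 9 mast cell genes (8 adjusted over the list alone; median 1.67; adjusted p = 0.560 with an estimated correlation). Without the muscle-rich libraries 4 of the 9 rose. Mitf, a transcription factor of melanocytes and mast cells, rose by 0.97 ± 0.28, the 1 called of 8 melanocytic genes. Lgals7, an epithelial galectin, fell from 77.4 ± 24.6 to 25.1 ± 6.45 CPM (-1.62 ± 0.28). Mmp2, a matrix metalloproteinase (0.58 ± 0.14), and Zbtb46, a dendritic cell transcription factor (0.66 ± 0.14), rose, as did endoglin, Eng (0.32 ± 0.08), the neural crest genes Nes (0.61 ± 0.17) and Tfap2b (0.40 ± 0.12) and the macrophage receptor gene Trem2 (0.59 ± 0.17), while Mertk, a receptor for dying cells, had -0.38 ± 0.11 and fell. The called genes described here for this comparison went the stated way in 6 of 6 tumours. No member of the T cell, cytotoxic, interferon or MHC presentation lists, which do not hold H2-M2, was called by edgeR in this comparison: medians were 0.51 for T cells and 0.34 for the interferon gamma list, and Pdcd1 (0.50 ± 0.41), Cd8a (0.67 ± 0.48), Cd274 (0.62 ± 0.27), H2-K1 (0.24 ± 0.17) and H2-Ab1 (0.48 ± 0.44) did not pass. Chka (-0.36 ± 0.12, adjusted p 0.0828), Pcyt1a (0.37 ± 0.12, 0.0827), Dhodh (-0.05 ± 0.11), Cad (-0.25 ± 0.11), Umps (-0.18 ± 0.12) and Ptgs2 (0.19 ± 0.84) did not pass.

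Across all genes, 382 rose and 426 fell in BRQ+PD-1 against PD-1. Lrrc4b, a synaptic adhesion gene, rose by 4.0 ± 0.56 from 0.116 ± 0.0995 to 1.92 ± 0.794 CPM, Scara5 by 3.14 ± 0.52 and H2-M2 by 3.12 ± 0.79. Large falls were the lectin gene Cd209f (-5.54 ± 1.51), the neuronal gene Stmn2 (-4.80 ± 1.30) and the chemokine gene Cxcl5 (-4.59 ± 1.15). Without PD-1 replicate 6, Cd209f had -2.19 (adjusted p 0.339) and Cxcl5 -2.16 (0.184), and without PD-1 replicate 5 Stmn2 had -3.37 (0.1). H2-M2 was called in 9 of 12 fits without 1 library, with adjusted p 0.0731 without BRQ+PD-1 replicate 3. The count of 808 became 425, 420 and 413 without PD-1 replicates 1, 2 and 6, 399 without BRQ+PD-1 replicate 3 and 502 without the 4 muscle-rich libraries.

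**Figure D4:**
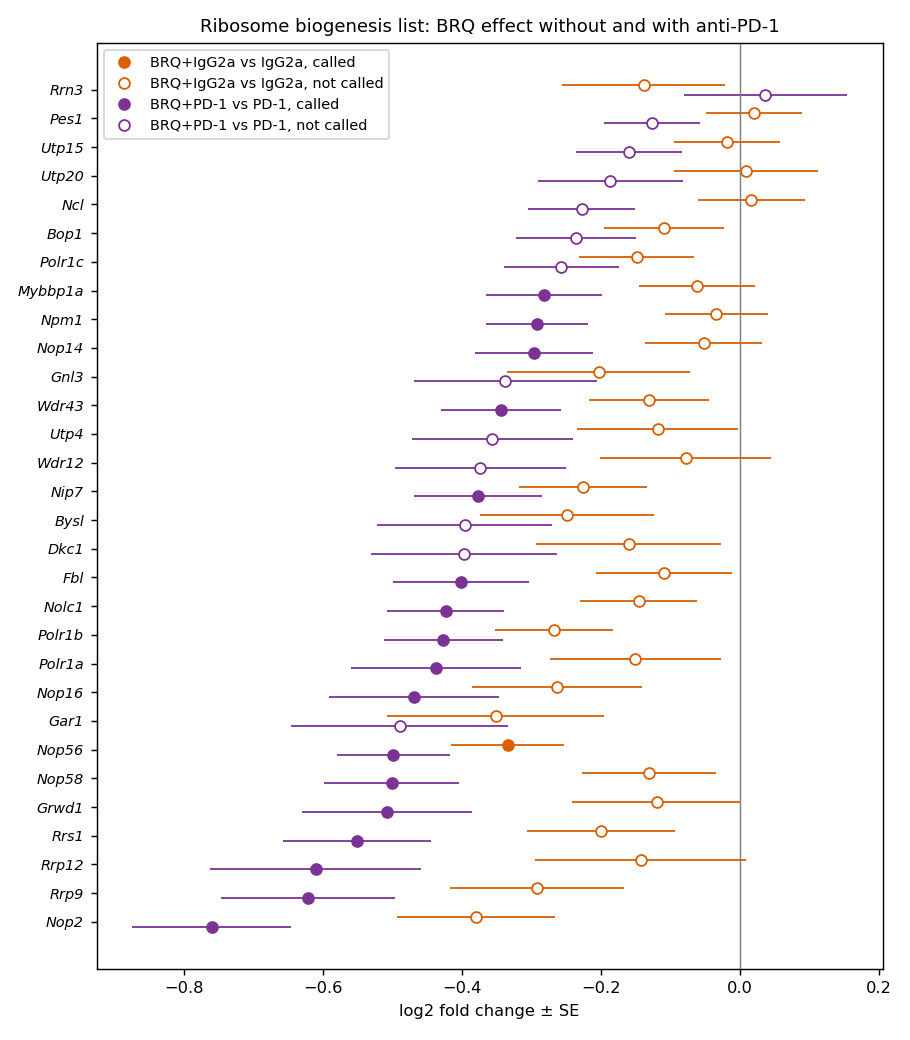
Log2 fold change ± SE of each of the 30 ribosome biogenesis genes, without anti-PD-1 (BRQ+IgG2a against IgG2a) and with it (BRQ+PD-1 against PD-1). Filled points are called genes and open points are genes not called. In BRQ+PD-1 against PD-1, 17 genes were called and the median was -0.39.

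The comparison of BRQ+PD-1 with BRQ+IgG2a asks what the antibody added to brequinar. No gene was called by edgeR among 16029, with 1168 at an unadjusted p under 0.05; DESeq2 called 4 genes and limma voom 612. Leaving out BRQ+IgG2a replicate 5 gave 65 genes and leaving out BRQ+PD-1 replicate 3 gave 1. Cd8a had -0.61 ± 0.48, Pdcd1 -0.51 ± 0.41, Cd274 -0.05 ± 0.27, H2-K1 -0.21 ± 0.17, H2-Ab1 -0.33 ± 0.44 and Dhodh -0.01 ± 0.11 (log2 ± SE, n = 6 each), with adjusted p of 0.729 or more. The type I interferon list had a median of -0.58 and the T cell list -0.59, with no member called over all genes or adjusted over the list alone. Camera at the preset correlation called 9 lists, 1 higher and 8 lower, and with an estimated correlation both had adjusted p = 0.946.

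Whether the brequinar effect differed with anti-PD-1 was tested by the interaction. It called 0 genes by edgeR, with 1222 at an unadjusted p under 0.05. DESeq2 called 13 and limma voom 268. By edgeR 1 gene was called without BRQ+PD-1 replicate 1, and 1 without the 4 muscle-rich libraries. None of the following passed: Pdcd1 had -1.71 ± 0.58 (adjusted p 0.534), Cd8a -1.51 ± 0.68, Cd274 -0.83 ± 0.38, H2-K1 -0.51 ± 0.24 and H2-Ab1 -1.53 ± 0.62. The interferon gamma list had 21 of 30 genes lower when adjusted over the list alone (median -1.15), the type I interferon list 18 of 30 (-0.97), MHC class II 7 of 12 (-1.31) and T cells 1 of 20 (-1.25), and none over all genes. Camera at the preset correlation called 17 lists, 3 higher and 14 lower. With an estimated correlation the interferon gamma and T cell lists had adjusted p = 0.316 and 0.324, so a difference of the effects was not shown for any gene or list by that test.

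Brequinar was compared in separate tumours without and with anti-PD-1, and the pair of comparisons shares no library. They called 98 genes in the same direction and 0 in opposite directions, 72 higher and 26 lower, where 11.3 and 2.1 would be shared by independent lists of those sizes. Of the 554 genes called without anti-PD-1, 519 had the same sign with it, and of the 808 called with it, 742 had the same sign without it. Across the 16029 genes, which are not independent replicates, log2 fold changes had r = 0.502, and 0.431 without the muscle-rich libraries, where 88 genes were shared. Scara5 (3.89 without and 3.14 with anti-PD-1), H2-M2 (4.01 and 3.12) and Scml4 (2.33 and 2.81) were among the shared rises, and Npl (-1.92 and -1.42), Chac1 (-1.37 and -1.48), Sesn2 (-0.66 and -0.94) and Nop56 (-0.33 and -0.50) among the shared falls. For anti-PD-1 without and with brequinar, 0 genes were shared by edgeR or DESeq2 and 1 by limma voom. By edgeR only 3 were called without brequinar and none with it, by DESeq2 35 and 4, and by voom 6 and 612.

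**Figure D5:**
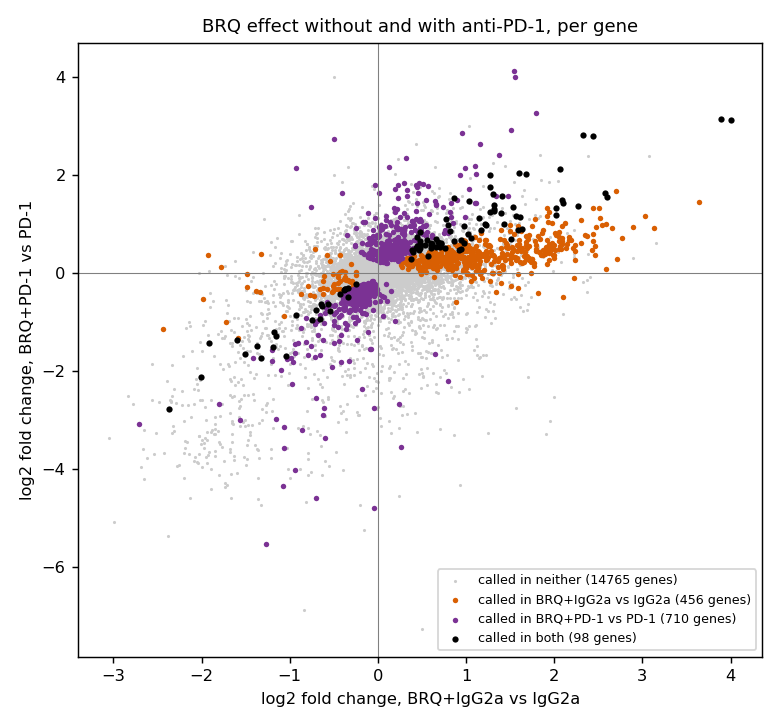
Log2 fold change of each gene with brequinar under the control antibody (x axis, BRQ+IgG2a against IgG2a) and under anti-PD-1 (y axis, BRQ+PD-1 against PD-1), with genes called in both comparisons marked. The 98 shared genes lie in the quadrants where both changes have the same sign, and r across all genes is 0.502.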

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

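Chosen after the result was seen were the test of muscle-rich libraries, the score differences against stromal and B cell genes, the test without the 2 libraries of lowest TMM factor, and the reassignments of tumours between BRQ+IgG2a and IgG2a. Single tumours far from the other 5 of their group were sought in 196 groups of 6 values with Dixon's ratio (gap to the nearest tumour over the range of the group) against its critical value for 6 samples. It was passed in 19 groups, where chance gives about 9.8.

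PD-1 replicate 6, a muscle-rich tumour, was highest of its group for 7 lists (mean log2 CPM, nearest tumour in brackets): macrophages 6.12 (5.16, ratio 0.846), B and plasma cells 3.65 (0.686, ratio 0.76), melanocytic genes 2.24 (1.3, ratio 0.758), fibroblasts 7.98 (7.3, ratio 0.718), nuclear oxidative phosphorylation 6.79 (6.54, ratio 0.71), endothelial cells 5.34 (4.6, ratio 0.679) and keratinocytes 2.15 (1.4, ratio 0.64). IgG2a replicate 2, also muscle-rich, was highest for cytotoxic lymphocytes at 1.5 (0.133, ratio 0.697), MHC class II presentation at 6.04 (5.11, ratio 0.688) and B and plasma cells at 1.06 (0.0133, ratio 0.665), and lowest for Cad at 6.3 (6.71, ratio 0.711). BRQ+IgG2a replicate 5, the library of lowest TMM factor, was lowest for mitosis genes at 4.97 (6.12, ratio 0.787) and S phase genes at 4.32 (5.06, ratio 0.653), and highest for ferroptosis defence genes at 6.6 (5.9, ratio 0.747). IgG2a replicate 1 was highest for de novo pyrimidine synthesis at 4.94 (4.82, ratio 0.719) and for Dhodh at 4.13 (3.78, ratio 0.651), and BRQ+PD-1 replicate 1 was lowest for Dhodh at 3.1 (3.61, ratio 0.665). PD-1 replicate 4 was highest for neural crest genes at 5.56 (5.44, ratio 0.724), and BRQ+PD-1 replicate 4 for adipocyte genes at 1.87 (0.00971, ratio 0.675).

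In the interaction of brequinar and anti-PD-1 camera at the preset correlation called 17 lists, among them the interferon gamma list (median log2 -1.15) and the T cell list (-1.25), both lower, and 0 lists with an estimated correlation or by fry. Reassigning the 24 tumours freely over the 4 groups gave as many lists in 24 of 100 assignments, up to 23. This also breaks up the effects of each treatment, so the share is no test of the interaction alone. Chance is not excluded.

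Muscle genes were high in 4 tumours. Of 20 other genes of mature muscle, listed before this test and not part of the muscle list, 20 had their lowest value in these 4 above their highest value in the other 20. This argues for skeletal muscle tissue in these 4 samples. How the tissue came into them cannot be told from these genes, and no biological explanation was tested.

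T cell, cytotoxic and interferon gamma genes were higher in BRQ+IgG2a than in IgG2a, with 45 of 71 members called and a median log2 fold change of 1.63. Without the muscle-rich libraries 44 of the 45 were still called, the median was 2.15 and 58 were called. These libraries include IgG2a replicate 2, the highest IgG2a tumour for cytotoxic genes (1.5, nearest 0.133). Its removal can by itself raise the difference, so this fit alone does not settle the role of muscle. With the muscle score as a covariate and all libraries kept, 550 of the 554 genes called in this comparison were still called. That argues against muscle as the whole cause. A lower share of tumour cells would raise stromal genes alike only if tumour cells do not express them, which was not tested. The T cell score minus the mean fibroblast and endothelial score was higher by 1.69 (-3.6 ± 0.92 against -5.29 ± 0.639, exact permutation p 0.00866, n = 6 each). Most of this is the T cell rise itself, as the fibroblast and endothelial scores differed by -0.04 and -0.09. A lower share of tumour cells is thus argued against only on that condition. Lymph node tissue would bring B cells, but the T cell score minus the B cell score was higher by 0.972 (1.79 ± 0.713 against 0.815 ± 0.303, exact permutation p 0.00649, n = 6 each). The B cell score was itself higher by 0.653, above the IgG2a mean in 5 of 6 tumours. The group difference therefore cannot rule out lymph node tissue in single tumours. More T cells in the tumours, or more transcript per T cell, both stay open as effects of brequinar.

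Ribosome biogenesis genes were lower in BRQ+PD-1 than in PD-1, with 17 of 30 members called and a median of -0.39. With the T cell score as a covariate 17 of the 17 were still called (median -0.39, 23 called in all), which argues against dilution of tumour RNA by T cells as the whole cause. Without the 2 libraries of lowest TMM factor 16 of the 17 were still called (median -0.41, 19 in all). Of 10000 random lists matched for GC content and transcript length 0% had so low a median, the lowest being -0.14. Without the muscle-rich libraries the median was -0.35 and 10 genes were called, with fewer libraries left. An effect of brequinar on growth or on the mix of cells stays open.

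Tumours were also reassigned in 100 ways per comparison, the real one included. As many called genes as the real assignment came in 1 of 100 for BRQ+IgG2a against IgG2a (real 554, highest other 332), 1 for PD-1 against IgG2a (3, 1), 1 for BRQ+PD-1 against IgG2a (627, 141) and 1 for BRQ+PD-1 against PD-1 (808, 351). This is the smallest share that 100 assignments can give, so chance is unlikely for these 4 counts but not excluded. The count of 3 for PD-1 against IgG2a also became 0 with no expression filter and with the replicate number block. The 98 genes shared by the brequinar comparisons were reached in 1 of 100 (highest other 0), which is no separate test of the overlap, since 6 and 5 of the 99 other assignments called any gene in the 2 comparisons. For BRQ+PD-1 against BRQ+IgG2a, for the interaction and for the anti-PD-1 overlap the real count was 0 by edgeR (1168 and 1222 genes at an unadjusted p under 0.05 in the first 2; DESeq2 called 4, 13 and 0), which 100 of 100 reached, with up to 2681, 371 and 0 genes. Of the 99 other assignments of BRQ+PD-1 against BRQ+IgG2a, 4 called any gene; a count of 2681 points to a structure of the samples outside the treatments. The assignments with 2681 and 1001 genes put both libraries of lowest TMM factor (BRQ+IgG2a replicate 5 and BRQ+PD-1 replicate 1) into BRQ+PD-1, but most assignments with that placement called no gene, so it is not the whole of the structure.

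For lists called at the preset correlation chance is not excluded in any comparison: as many came in 70 of 100 assignments for BRQ+IgG2a against IgG2a (real 14, highest other 23), 8 for PD-1 against IgG2a (20, 22), 16 for BRQ+PD-1 against IgG2a (18, 25), 76 for BRQ+PD-1 against PD-1 (10, 23) and 81 for BRQ+PD-1 against BRQ+IgG2a (9, 24). The number of called lists therefore carries no weight by itself. Called members of each list were not counted in the reassignments, so their number was not tested this way.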

How the results depend on the processing

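Leaving out the 4 muscle-rich libraries or the 2 of lowest TMM factor, the muscle score as a covariate, the permutation test of list scores and the contrasts of each treatment averaged over the other were chosen after seeing the data. Relative log expression factors and a fit without robust dispersion kept the counts of genes within 1.5 times. Of the called results for named genes, DESeq2 called 247 again and lost 0, voom called 233 and lost 16, the muscle covariate lost 26, leaving out the lowest TMM factors 26, no expression filter 84, the replicate number block 88, leaving out the muscle-rich libraries 62, and fits of the 2 groups alone 50 while calling 100. Fits without 1 library called 225 and lost 123. No called result for a named gene reversed its direction under the settings tried; single libraries were left out only for the called genes of largest change.

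Genes called in BRQ+IgG2a against IgG2a numbered 554, and 337 with the 2 groups alone, 1370 without the lowest TMM factors, 857 with the muscle covariate, 888 by DESeq2 and 2100 by limma voom; the 79 falls among them became 466 without the lowest TMM factors, 188 by DESeq2 and 758 by voom. In PD-1 against IgG2a the 3 became 0 with no expression filter (where 2142 genes had an unadjusted p under 0.05 by edgeR), 35 by DESeq2 and 6 by voom. In BRQ+PD-1 against IgG2a the 627 became 297 with no filter, 371 with the 2 groups alone, 404 without the muscle-rich libraries, 1564 by DESeq2 and 1444 by voom; the share of higher genes was 63.5% by edgeR and 46% by DESeq2. In BRQ+PD-1 against PD-1 the 808 became 431 with no filter, 360 with the 2 groups alone, 502 without the muscle-rich libraries, 1406 by DESeq2 and 2181 by voom. With no filter more genes are tested, and 2 groups alone leave fewer residual degrees of freedom. The cause was not tested for any of these changes.

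In BRQ+PD-1 against BRQ+IgG2a the 0 genes became 7 without the lowest TMM factors, 4 by DESeq2 and 612 by voom. In the interaction the 0 became 1 without the muscle-rich libraries, 13 by DESeq2 and 268 by voom. For brequinar averaged over both antibodies the 2001 became 3763 by voom, and for anti-PD-1 averaged with and without brequinar the 0 became 1 without the muscle-rich libraries, 8 without the lowest TMM factors, 16 by DESeq2 and 59 by voom. The brequinar overlap of 98 became 57 with no filter, 199 by DESeq2, 431 by voom and 198 without the lowest TMM factors, and the anti-PD-1 overlap of 0 became 1 by voom. The cause was not tested.

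Called lists depended on the test most: an estimated correlation called 0 in every contrast. The rotation test fry called 9 in BRQ+IgG2a against IgG2a, 0 in PD-1 against IgG2a, 6 in BRQ+PD-1 against IgG2a, 5 in BRQ+PD-1 against PD-1, and 0 in BRQ+PD-1 against BRQ+IgG2a, in the interaction and in the anti-PD-1 average; in the brequinar average it called 17, against 16. Exact permutation called 0, 0, 0, 2 and 0 in the 5 pairwise comparisons. The 10 lists of BRQ+PD-1 against PD-1 became 16 with no filter and 17 without the muscle-rich libraries, and the 6 of the anti-PD-1 average became 10 without these and 14 with the muscle covariate. The nuclear oxidative phosphorylation list reversed its direction without the muscle-rich libraries, at adjusted p 0.953 in BRQ+IgG2a and 0.271 in PD-1 against IgG2a; the cause was not tested.

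Leaving out each library in turn gave 258 to 1179 genes in BRQ+IgG2a against IgG2a, 0 to 2 in PD-1 against IgG2a, 256 to 783 in BRQ+PD-1 against IgG2a, 399 to 1083 in BRQ+PD-1 against PD-1, 0 to 65 in BRQ+PD-1 against BRQ+IgG2a and 0 to 1 in the interaction. The counts of 783 and 1083 came without BRQ+PD-1 replicate 4; the report names the libraries that moved a count by over 1.5 times. Lists ranged over 14 to 17, 16 to 20, 14 to 20, 8 to 20 (20 without PD-1 replicate 6), 7 to 13 and 10 to 21 (10 without PD-1 replicate 1).

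Whether replicate numbers pair the tumours was checked across groups: the 36 correlations between tumours of equal number ran from -0.64 to 0.444, 15 were above 0.1, and 1 of 24 tumours was closest to its own number, so the report uses no pairing. With replicate number as a block, genes called were 361 in BRQ+IgG2a against IgG2a (355 of the 554), 0 in PD-1 against IgG2a, 285 in BRQ+PD-1 against IgG2a (285 of the 627), 411 in BRQ+PD-1 against PD-1 (406 of the 808), 0 in BRQ+PD-1 against BRQ+IgG2a, 0 in the interaction, and 1412 and 0 for the 2 averages. Lists were 15, 20, 19, 13, 10, 17, 17 and 7 in the same order, and the overlaps 50 and 0. The block leaves fewer residual degrees of freedom.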

Other observations

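In this part the contrasts of each treatment averaged over the other were chosen after the data were seen; the score correlations were written down before their values were seen.

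Brequinar averaged over both antibodies called 2001 genes, 1108 higher and 893 lower. Scara5 rose by 3.51 ± 0.37 (log2 ± SE, 12 against 12 tumours), H2-M2 by 3.57 ± 0.58 and Iglon5 by 2.62 ± 0.33. Of 30 ribosome biogenesis genes 18 fell, with Nop2 at -0.57 ± 0.08 and Nop56 at -0.42 ± 0.06, and of 26 integrated stress response genes 11, with Chac1 at -1.43 ± 0.26 and Shmt2 at -0.52 ± 0.10. T cell genes rose in 14 of 20 and interferon gamma genes in 19 of 30. These rises rest mostly on the tumours without anti-PD-1. The T cell and interferon gamma scores differed by 1.625 and 1.403 in BRQ+IgG2a against IgG2a. In BRQ+PD-1 against PD-1 they differed by 0.374 and 0.276, with no member of either list called. Mast cell genes Tpsb2 (1.04 ± 0.31), Tpsab1 (1.06 ± 0.34) and Cpa3 (1.14 ± 0.37) rose, 3 of 9. Dpyd, the pyrimidine-degrading dehydrogenase, rose by 1.22 ± 0.34. As many genes came in 1 of 100 reassignments of the tumours (highest other 7), the smallest share that 100 can give, so chance is unlikely. The 16 called lists were reached in 33 (highest other 22), and with an estimated correlation none was called. Without the 4 muscle-rich libraries the 2001 called genes became 1642, 1057 higher and 585 lower, with 1255 of the 2001 among them. The number of falls thus depends in part on those libraries.

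Anti-PD-1 averaged with and without brequinar called 0 genes by edgeR, with 1229 at an unadjusted p under 0.05, 16 by DESeq2 and 59 by voom. All 100 of 100 reassignments reached that count, up to 1981, and its 6 lists were reached in 91 (highest other 22). Of the 99 others 5 called any gene; a count of 1981 points to a structure of the samples. All 5 put both libraries of lowest TMM factor into the same group, but most assignments that did so called no gene.

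A hypothesis was that tumours with more T cell transcript also have more interferon response within their group. Scores of the T cell and interferon gamma lists, centred on group means, had r = 0.903 over the 24 tumours (Spearman 0.914; permutation p 0.00001, the smallest that 100000 permutations can give), and 0.877 without the 2 tumours farthest out. Interferon gamma made by T cells may link these scores, which the correlation alone does not show, and tumour purity could move both.

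Another hypothesis was that ribosome biogenesis is lower where T cells or fewer dividing cells are present. T cell and ribosome scores had r = -0.0788 (permutation p 0.732) and mitosis and ribosome scores r = -0.051 (permutation p 0.834), so neither relation was shown over all tumours. By group, mitosis and ribosome scores had r = 0.776 in PD-1, 0.74 in BRQ+PD-1, 0.0186 in IgG2a and -0.512 in BRQ+IgG2a (n = 6 each, not tested). T cell and ribosome scores had r = 0.306 in PD-1, -0.0405 in BRQ+PD-1, 0.319 in IgG2a and -0.687 in BRQ+IgG2a (n = 6 each, not tested). Without BRQ+IgG2a replicate 5 and BRQ+PD-1 replicate 5 the value over all remaining tumours for mitosis and ribosome scores was 0.314 (permutation p 0.0492, not adjusted).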
